A study of Mus musculus with 30 samples.

How the data were processed

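Total RNA and ribosome footprints were measured in testis of juvenile Ythdc2 knockout mice and their controls, and total RNA in adult Ythdc2 WLA mice, all labelled C57BL/6J. Reads were aligned with STAR to mm10 and adult libraries compared with DESeq2, per the submitters' processing notes; versions, counting program and annotation release are not given in the sources used here. RNA was extracted with Trizol and depleted of ribosomal RNA or selected for poly(A), per the labels' protocols, which do not say which was used for which library.

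The adult table deposited by the authors holds raw read counts for 55566 features in 6 libraries, 165 of them piRNA clusters that may overlap genes, and the authors' log2 fold changes and p-values from DESeq2. Its columns give genotype and not animal, so age could not be a covariate. Per the labels, ages were balanced between the genotypes. The juvenile tables deposited by the authors hold effects and adjusted p-values of anota2seq 1.14.0 for 15145 genes at day 8 and 14846 at day 10, for total RNA, footprints, translation and buffering, per the file headers and description. The base of these deposited effects is not stated; they were read as log2, because genes in the authors' translation class all differ by at least 0.263, the log2 of 1.2, between footprints and total RNA. Their standard deviation over genes was 0.057 at day 8 and 0.067 at day 10 in total RNA, and a transformation before the model may have shrunk them, so they are not to be read as plain folds. The description names knockout first, and the direction was taken from it. Day 10 controls were heterozygous and wild type together.

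Adult counts were filtered with edgeR's filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood test, homozygous against heterozygous, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. DESeq2 1.42.0 served as an alternative. The biological coefficient of variation was 6.8%. On simulated counts for the 22446 adult features with dispersions from the trend, the test recovered 32%, 60%, 82% and 100% of features changed 1.25, 1.5, 2 and 4 times, with 7 false among 144 calls; with dispersions per feature it recovered 34%, 56%, 84% and 96%, with 15 false among 150. The labels number animals, so replicates were taken as separate animals. No pair of libraries of a group agreed within sampling noise (chi-square per degree of freedom of 1.79 or more). No new test of single genes was made on the juvenile tables.

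There were 27 gene lists fixed before the data were examined, tested with cameraPR of limma 3.58.1 (preset correlation 0.01, two-sided, Benjamini-Hochberg over all lists and comparisons). The plan was to rank genes by a signed normal score of the p-value; the juvenile tables hold adjusted p-values with many ties, so their effects were ranked, and the score of the adjusted p was run as an alternative chosen after seeing the data. On day 10 total RNA effects permuted over 14846 genes, 4 of 200 random lists of 40 had a p under 0.05. In the same run 100 of 100 lists shifted by 0.1 were found. Permutation removes correlation between genes, so this run could not show whether the preset of 0.01 is too low. Correlations estimated from the adult libraries ran from -0.00375 to 0.842 over lists, with 0.132 for the early meiotic list. None could be estimated for the juvenile tables, so their list p-values may be too small. Adult lists were also tested with a correlation estimated from the libraries. They were tested with fry of limma too, for a shift in 1 direction and, in its mixed form, for changes in either direction. Adult CPM of single genes were scaled by TMM, and adult list levels are means of log2(CPM + 1) with library totals as they stand.

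Genes named in the text were Ythdc2, Meioc, Rbm46 and Xrn1; the 6 higher and 6 lower genes with the largest effect past an adjusted p of 0.05 that carry a proper symbol and, in adult, reach the median level with groups that do not overlap; and up to 3 members past 0.05 of each of the 8 lists with the smallest p, with up to 2 members that moved against the majority. Other names were chosen after their values were seen. Ages and alleles were compared by Spearman correlation across genes and by overlaps of calls with Fisher's exact test. The slope of the authors' regression was worked back for each gene as (footprint effect minus translation effect) divided by the total RNA effect. Gene positions came from an annotation of GRCm38.p6, the same assembly as mm10, for 98.7% of juvenile genes. For positions, the mean absolute effect within 20 Mb of Ythdc2 was ranked among windows of 40 Mb on other chromosomes; with effects permuted over genes, 0 of 20 runs ranked it above the 95th percentile. Calculations outside R used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9. Alternatives were other thresholds, a minimum fold change, scaling, filters, DESeq2, leaving out each adult library and other list statistics.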

Results

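The series measured RNA in the testis of mice that carry changed alleles of Ythdc2, which encodes an RNA helicase with a YTH domain that is needed for germ cells to carry through entry into meiosis. There were 30 libraries. At postnatal day 8 and day 10, 12 total RNA libraries and 12 ribosome footprint libraries were made from the same animals, footprints being the stretches of mRNA that ribosomes shield from nuclease. Day 8 had 3 homozygous knockout and 3 wild-type animals, and day 10 had 3 homozygous knockout, 2 heterozygous and 1 wild-type animal. Adult testis gave 6 RNA libraries, 3 from mice homozygous and 3 from mice heterozygous for the Ythdc2 WLA allele, aged 20 or 24 weeks. The adult libraries held between 33331987 and 43707798 counted reads. For the juvenile libraries the authors' effects and adjusted p-values were used, so their depth is unknown here and no spread between animals can be given. Ythdc2 lies on chromosome 18, from 44827730 to 44889720 of mm10. Its level in the juvenile libraries was not analysed here, so the knockout could not be checked on its own transcript.

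The day 10 comparison asks which transcripts differ in testis without Ythdc2 when germ cells of normal testis are entering meiotic prophase. Early meiotic genes were lower in knockout testis. The list of meiotic entry and prophase had 43 measured genes, among them genes of chromosome axes, synapsis and early recombination. Over these 43 genes the median total RNA effect computed from the authors' deposited table was -0.30 (log2, knockout against control), with quartiles of -0.43 and -0.20. Of these genes 39 lay below 0 (cameraPR, adjusted p 3.46e-176). Footprints moved the same way, with a median of -0.36, and 41 of 43 genes lay below 0 (cameraPR, adjusted p 1.3e-101). The test ranks genes against each other and does not contain the spread between animals.

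No single gene passed an adjusted p of 0.05 in total RNA at day 10 in the authors' deposited table (anota2seq), where the smallest was 0.0546; no unadjusted p was used here. At the looser planned threshold of 0.1, 24 genes passed, 12 higher and 12 lower. Among the lower ones in the authors' deposited table were Meiob, which encodes a single-strand DNA binding protein of meiotic recombination, at -1.16, and Gm4969, also known as Meiosin, a transcription factor of meiotic entry, at -1.05. The authors' deposited table also gave Terb1, which ties telomeres to the nuclear envelope, at -0.66, Spata22 at -0.48, the histone methyltransferase gene Prdm9 at -0.40 and Majin at -0.32. Mybl1, the gene of a transcription factor of pachytene spermatocytes, stood at -0.31 in the authors' deposited table. Outside the meiotic list, the steroid enzyme gene Hsd17b1 (-0.41) and Pparg (-0.37) were lower, and Clec2d (0.55), Cd74 (0.48), Synpo (0.37), Aldh7a1 (0.35), Lama5 (0.28) and Cyp26a1 (0.26) were higher in the authors' deposited table. These genes were named at the looser threshold after their values were seen. At least Cd74 and Synpo of them lie on chromosome 18 within 20 Mb of Ythdc2. So does Fbn2, which was lower (-0.25, anota2seq adjusted p 0.0924) in the authors' deposited table.

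Not all genes near meiotic entry followed this direction. Rec8, which encodes a meiotic cohesin subunit, had a total RNA effect of 0.27 and Stra8, the retinoic acid induced gatekeeper of meiosis, one of 0.20 in the authors' deposited table. The list of retinoic acid synthesis, breakdown and response was higher as a group, with 14 of 17 genes above 0 and a median of 0.06 (cameraPR, adjusted p 2.81e-06). Differentiating spermatogonia (median 0.04, adjusted p 0.171), undifferentiated spermatogonia (median 0.02, adjusted p 0.874) and the piRNA pathway (median 0.001, adjusted p 0.959) did not pass cameraPR. Sertoli cell markers (median -0.01, adjusted p 0.809) and Leydig cell markers (median 0.01, adjusted p 0.492) did not pass either. Red blood cell genes were higher, with all 5 above 0 and a median of 0.14 (cameraPR, adjusted p 0.000146). Ribosomal protein genes, many of which share reads with pseudogenes, had a median of -0.03 with 69 of 78 below 0 (cameraPR, adjusted p 0.00658; 0.272 with a preset correlation of 0.05). The list of interstitial fibroblast and epididymal genes passed (cameraPR, adjusted p 0.00328) with a median of -0.002 and a mean of -0.08, and its lowest member in the authors' deposited table was the epididymal gene Crisp1 at -0.70; the call was lost in the rank version (adjusted p 0.727). Of the genes named before the data were examined as acting with YTHDC2, Meioc stood at -0.08, Rbm46 at 0.002 and Xrn1 at 0.001 in the authors' deposited table.

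**Figure D1:**
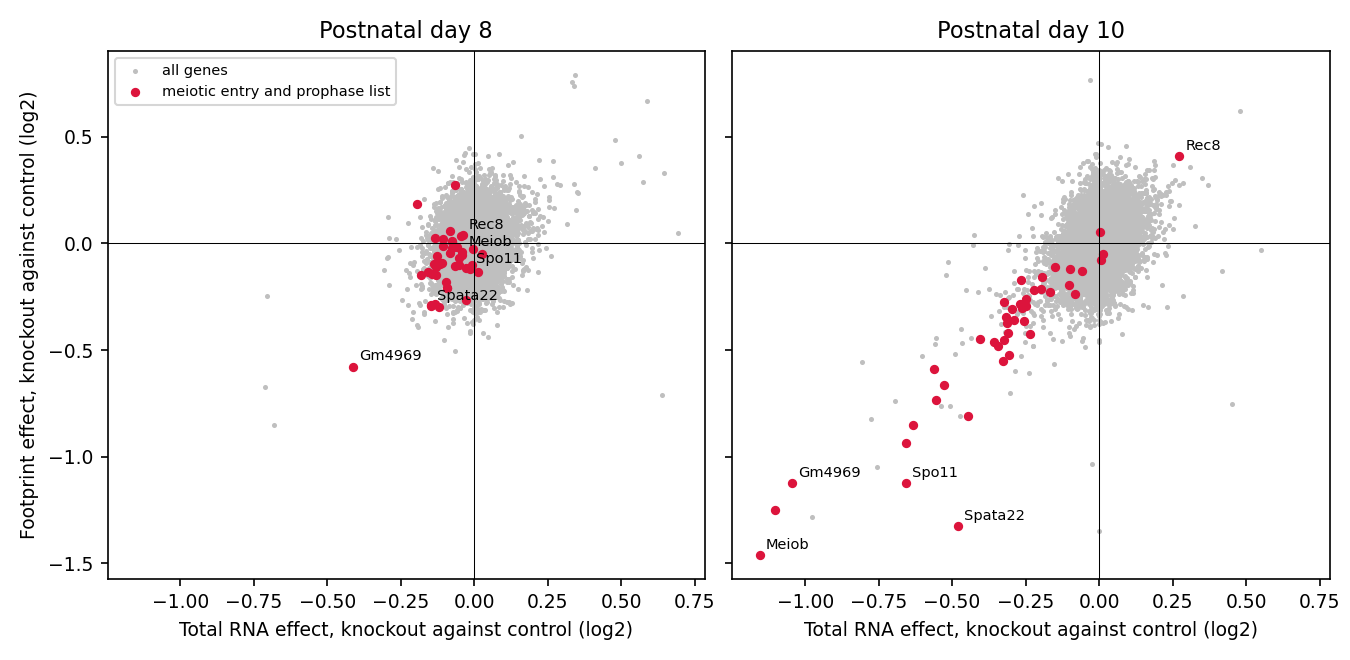
Deposited total RNA effect (x axis, log2, knockout against control) against footprint effect (y axis, log2) for each gene at day 8 and day 10; grey points are all genes and red points the 43 genes of the meiotic list. At day 10, 39 of the red points lie below 0 in total RNA, and Rec8 lies above 0 in both.

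In day 10 footprints no gene passed 0.05 or 0.1 in the authors' deposited table (anota2seq), and 4 passed 0.15, all lower in the knockout. These were Spo11, the enzyme that makes meiotic double-strand breaks, at -1.12, Gm4969 at -1.12, Spata22 at -1.32 and Gm49340 at -1.35 in the authors' deposited table. Spo11 and Spata22 had total RNA effects of -0.66 and -0.48 in the authors' deposited table, whereas Gm49340 stood at 0.0005. Red blood cell genes were again higher, with a median of 0.22 over 5 genes (cameraPR, adjusted p 0.0014; 0.0887 with a score of the adjusted p). Meioc (-0.01), Rbm46 (-0.01) and Xrn1 (0.03) had small footprint effects in the authors' deposited table.

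At day 8, 8 genes passed an adjusted p of 0.05 in total RNA in the authors' deposited table (anota2seq), 4 higher and 4 lower in the knockout. Lower in the authors' deposited table were Cdo1, which encodes cysteine dioxygenase, at -0.71, the protocadherin Pcdhgb6 at -0.71, the aminopeptidase gene Lvrn at -0.68 and Gm4969 (Meiosin) at -0.41. Higher in the authors' deposited table were Clec2d, a C-type lectin, at 0.69, the carbonic anhydrase gene Car3 at 0.65, the fatty acid binding protein gene Fabp4 at 0.57 and Slfn5 at 0.34. Cdo1, Lvrn and Pcdhgb6 lie on chromosome 18, as does Ythdc2, and Pcdhgb6 shares exons and reads with other genes of its cluster. Of the 100 genes with the largest total RNA effects at day 8, 25 lay within 20 Mb of Ythdc2, 16 of them higher; among those in the authors' deposited table were Stk32a (0.56), Synpo (0.50), Cd74 (0.34) and Camk4 (0.27). At day 10 the count was 7 of 100, 5 of them higher. Meioc (-0.01), Rbm46 (-0.02) and Xrn1 (0.08) did not pass in the authors' deposited table.

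**Figure D2:**
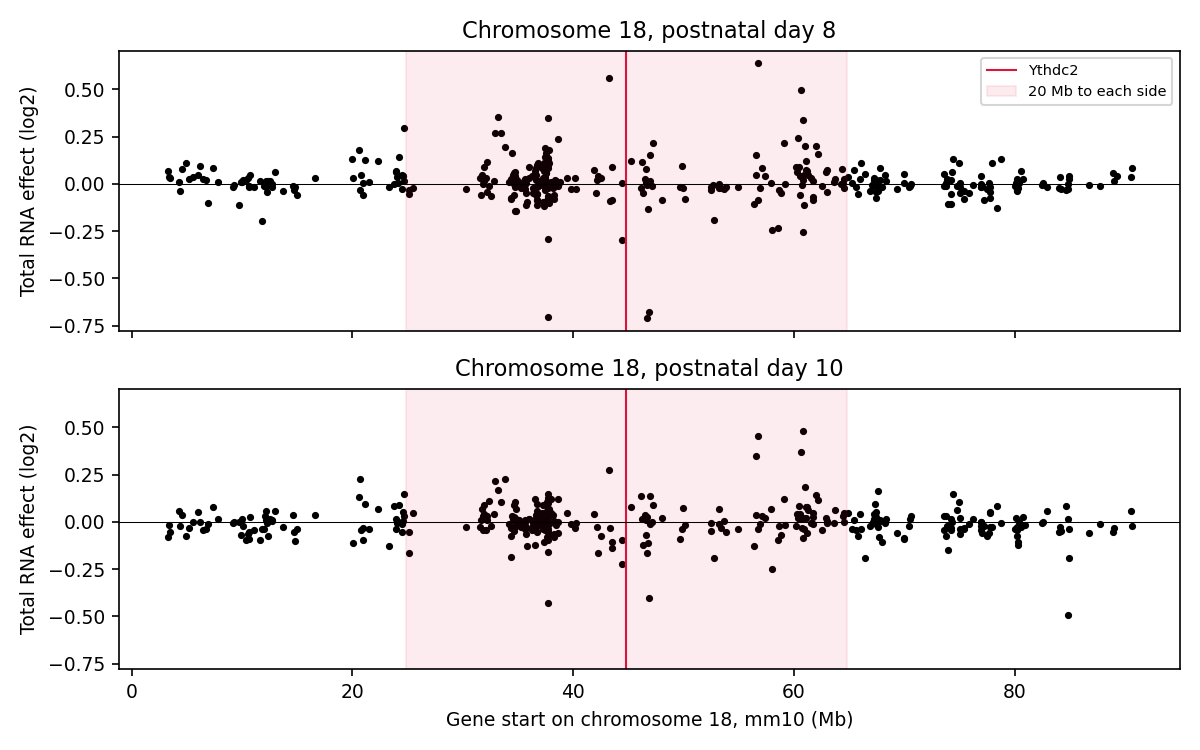
Deposited total RNA effect (y axis, log2, knockout against control) of each gene on chromosome 18 by its start (x axis, Mb, mm10) at day 8 and day 10; the line marks Ythdc2 and the shading 20 Mb to each side. Cdo1 at -0.71 and Lvrn at -0.68 stand among the lowest points of day 8.

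The early meiotic list was lower at day 8 as well. Its median total RNA effect was -0.09, and 41 of 43 genes lay below 0 (cameraPR, adjusted p 1.04e-17). Gm4969 was its single member past 0.05, and Prdm9 stood at -0.19 in the authors' deposited table. Markers of differentiating spermatogonia were lower, with 15 of 16 below 0 and a median of -0.07 (cameraPR, adjusted p 5.86e-06); examples in the authors' deposited table were Crabp1 (-0.19), Rhox13 (-0.18) and Sohlh2 (-0.09). Undifferentiated spermatogonia (median 0.02, adjusted p 0.16) and piRNA pathway genes (median -0.004, adjusted p 0.753) did not pass cameraPR. Genes of mitotic progression had a median of -0.05 (24 of 30 below 0, cameraPR, adjusted p 0.0045; 0.101 with a preset correlation of 0.05), nuclear genes of oxidative phosphorylation one of -0.05 (56 of 61 below 0, adjusted p 1.51e-05) and ribosomal protein genes one of -0.07 (76 of 78 below 0, adjusted p 1.9e-17).

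Some lists of cells outside the seminiferous tubule moved at day 8 too. Endothelial markers had a median of -0.11 (11 of 12 below 0, cameraPR, adjusted p 4.08e-07). Red blood cell genes had one of -0.17 (6 of 6 below 0, adjusted p 2.36e-08), opposite to day 10. Leydig cell markers were higher, with a median of 0.03 and 10 of 15 above 0 (cameraPR, adjusted p 1.91e-05); the largest values in the authors' deposited table were Cyp17a1 at 0.59 and Star at 0.28. The Leydig call was lost in the rank version of the test (adjusted p 0.202). Interferon-stimulated genes had a median of 0.06 with 12 of 14 above 0 (cameraPR, adjusted p 0.000792), led in the authors' deposited table by Rtp4 at 0.23 and Oasl2 at 0.14. Sertoli cell markers did not pass (median 0.002, adjusted p 0.959). Neither did macrophage markers (median 0.045, cameraPR, adjusted p 0.148), interstitial fibroblast and epididymal genes (median 0.006, adjusted p 0.733) and peritubular myoid markers (median -0.01, adjusted p 0.959).

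In day 8 footprints no gene passed 0.15 in the authors' deposited table (anota2seq), where the smallest adjusted p was 0.254. Replication-dependent histone genes, whose mRNAs lack poly(A) tails, were lower as a group, with 42 of 42 below 0 and a median of -0.21 (cameraPR, adjusted p 8.18e-32), while their median in total RNA was -0.005 (adjusted p 0.733). Reads of these genes are shared between near-identical copies, so the 42 values are not independent. The early meiotic list had a median footprint effect of -0.10 with 34 of 43 below 0 (cameraPR, adjusted p 7.83e-07), and differentiating spermatogonia one of -0.10 with 13 of 16 below 0 (adjusted p 0.00623). Both calls were lost with a score of the adjusted p, an alternative chosen after seeing the data (adjusted p 0.105 and 0.316). That of differentiating spermatogonia was also lost with a preset correlation of 0.05 (cameraPR, adjusted p 0.0566). The macrophage list passed (cameraPR, adjusted p 0.0399) with a median of -0.01 and a mean of 0.08, lost in the rank version (adjusted p 0.767). Its member Cd74, which lies on chromosome 18 within 20 Mb of Ythdc2, stood at 0.74 in the authors' deposited table. Meioc (-0.26), Rbm46 (-0.04) and Xrn1 (0.10) did not pass in the authors' deposited table.

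**Figure D3:**
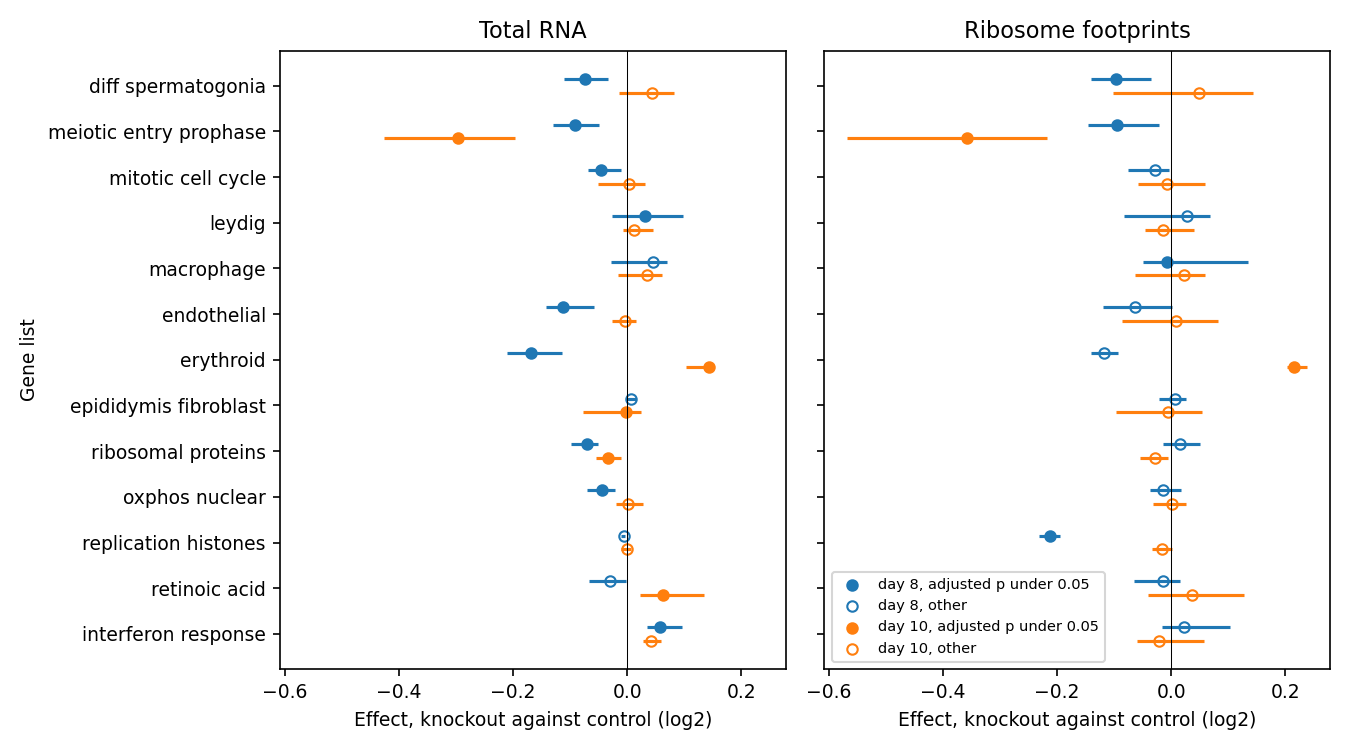
Median effect (points, log2, knockout against control) and quartiles over genes (bars) of each gene list that passed in total RNA or footprints at either age; filled points have a cameraPR adjusted p under 0.05. The early meiotic list has medians of -0.09 at day 8 and -0.30 at day 10 in total RNA, and red blood cell genes change from -0.17 to 0.14.

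Translation, the footprint change that remains after regression on total RNA, was tested by the authors with anota2seq. At day 8 the authors' deposited table held 202 genes past an adjusted p of 0.05, 101 higher and 101 lower, and at day 10 398 genes, 201 higher and 197 lower. Many of these genes had small measured changes. Upk1b, which encodes a uroplakin, had a translation effect of -20.61 at day 8 in the authors' deposited table with a total RNA effect of 0.09 and a footprint effect of -0.15. Of the 202 genes 128 had the sign of their footprint effect minus their total RNA effect, and of the 398 genes 252 did. Over all genes this held for 11500 of 15145 at day 8 and 11460 of 14846 at day 10, a larger share than among the called genes. The authors' own class of translationally changed genes holds adjusted p up to 0.099 and leaves out genes with a small difference between footprint and total RNA effects. It held 25 genes at day 8, 10 of them among the 202, and 53 at day 10, 23 of them among the 398.

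The largest translation effects at day 8 in the authors' deposited table were Gprin3 (9.66), Ganc (7.23), Wrnip1 (6.93), Terb1 (5.02), Il17d (3.66) and Dyrk2 (2.80) among the higher genes. Among the lower genes of day 8, Upk1b was followed by Sez6 (-11.24), Mill2 (-5.84), Prdm9 (-4.92), Sfxn4 (-3.68) and Hormad2 (-3.51) in the authors' deposited table. These are signs of what remains after regression, and the measured effects did not always follow them. Gprin3 had a total RNA effect of 0.17 and a footprint effect of 0.06 in the authors' deposited table. Prdm9 had -0.19 and 0.18 there, and Terb1 -0.09 and -0.21. Others had the sign of footprint minus total RNA, such as Dyrk2 (0.09 and 0.2) and Wrnip1 (-0.05 and 0.04). The meiotic list had a median translation effect of -0.10 at day 8 (cameraPR, adjusted p 0.000146), with 2 members higher, 4 lower and 37 not past 0.05. In translation effect, Terb1 and Msh5 (0.99) went against the list in the authors' deposited table. Lower in translation effect in the authors' deposited table were Lhx1 (-1.84) and Tspan8 (-1.03) of undifferentiated spermatogonia, Aurkc (-0.89) of the pachytene list and Rtp4 (-0.63) of the interferon list. The meiotic call was lost when footprint minus total RNA was ranked in its place (adjusted p 0.90). At day 10 the higher genes in the authors' deposited table were led by Lrp4 (8.04), Efnb2 (7.40), Zfc3h1 (6.36), Zfp322a (3.92), Tgfbr1 (3.41) and Ehd1 (3.35). The lower ones of day 10 in the authors' deposited table were Rpl24 (-5.81), Tbata (-4.60), Cmss1 (-3.54), Syk (-3.40), Clmn (-3.19) and Dynlt1c (-2.74). The meiotic list had a median translation effect of -0.01 at day 10 (cameraPR, adjusted p 0.416), with Majin (-0.92), Prdm9 (-0.79) and Spo11 (-0.60) past 0.05 in the authors' deposited table. In the other lists with the smallest p, members past 0.05 were Cd74 (1.42) and Rpl28 (0.54) among the higher genes and Casp8 (-1.40), Cx3cr1 (-1.07), Hba-a2 (-0.80), Ccnd2 (-0.63) and Pou5f1 (-0.50) among the lower ones in the authors' deposited table. The round spermatid, DNA replication, peritubular myoid, histone and retinoic acid lists also had members past 0.05, among them Cyp26a1, a retinoic acid breakdown enzyme gene, at 1.56 in the authors' deposited table. In the authors' class of day 10, Mtx1 had a footprint effect of -1.03 with a total RNA effect of -0.02 in the authors' deposited table.

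The ages were set side by side on 14607 genes. Across genes, which are not independent replicates, total RNA effects of day 8 and day 10 had a Spearman correlation of 0.111, footprints 0.03 and translation effects 0.006. At an adjusted p of 0.15, 4 genes were higher in total RNA at both ages where independent lists would share 0.0955 (one-sided Fisher's exact test, p 1.99e-06). Lower at both ages were 2 genes, against 0.0349 (p 0.000476). Of these 6 genes 4 lie within 20 Mb of Ythdc2, namely Cd74, Synpo and Marchf3 among the higher ones and Lvrn among the lower ones. Without the genes of that region, an alternative chosen after seeing the data, Clec2d was shared among the higher genes (expected 0.0557, p 0.0543) and Gm4969 among the lower genes (expected 0.00681, p 0.00681). Translation calls at 0.05 shared 1 higher gene (expected 1.34, p 0.742) and 3 lower genes (expected 1.3, p 0.142), and 3 genes were called in opposite directions. At 0.15 they shared 11 higher genes (expected 6.69, p 0.0732) and 14 lower genes (expected 7.2, p 0.0136), and 14 were called in opposite directions.

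The adult comparison asks whether testis homozygous for the WLA allele differs from heterozygous testis. Ythdc2 itself had 33.3 ± 3.03 CPM (read counts per library size scaled by TMM) in heterozygous and 34.1 ± 1.54 in homozygous testis (SD, n = 3 each; log2 fold change 0.03 ± 0.07 SE, edgeR adjusted p 0.883). Meioc (0.06), Rbm46 (0.03) and Xrn1 (-0.04) had small log2 fold changes with edgeR adjusted p of 0.622, 0.879 and 0.822. The meiotic list that was lower in the juvenile knockout had a median of 0.04 over 44 genes (cameraPR, adjusted p 0.733). It did not pass fry for a shift in 1 direction (adjusted p 0.803), where the smallest adjusted p of any list was 0.427. In the mixed form of fry, for changes in either direction, it passed (adjusted p 0.0365). DNA replication (0.0408), piRNA pathway (0.0408) and peritubular myoid (0.0452) lists passed the mixed form of fry as well. A list without a shared direction may thus still hold changed members. Of 22446 features tested, 53 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 21 higher and 32 lower in homozygous testis.

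Changes of the named genes, which were limited to genes at or above the median level, were moderate. Among all calls the largest absolute log2 fold change was 1.36, and 7 calls reached at least 1. Pcnx2, a pecanex family gene, rose from 15.7 ± 0.559 to 28.9 ± 2.29 CPM (SD, n = 3 each; log2 fold change 0.88 ± 0.07 SE, edgeR adjusted p 0.00114). The chromatin remodelling gene Dpf3 rose from 42.2 ± 0.443 to 60.3 ± 1.70 (SD, n = 3 each; log2 fold change 0.51 ± 0.05 SE, edgeR adjusted p 0.00178). Gucy2g, a guanylate cyclase gene, rose with a log2 fold change of 0.77, Pgf, which encodes placental growth factor, with 0.59, Iglon5 with 0.59 and Rundc3a with 0.57. Col14a1, a collagen gene, fell from 13.2 ± 0.886 to 7.29 ± 1.04 CPM (SD, n = 3 each; log2 fold change -0.86 ± 0.11 SE, edgeR adjusted p 0.0105). The mitochondrial malic enzyme gene Me3 (-0.68), Pcare (-0.59), the heparan sulphate enzyme gene Ndst4 (-0.56), Epyc (-0.52) and Klrb1 (-0.50) fell as well. These 12 genes were chosen among those whose groups did not overlap, which held for 19.3% of tested features where chance gives 10%.

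**Figure D4:**
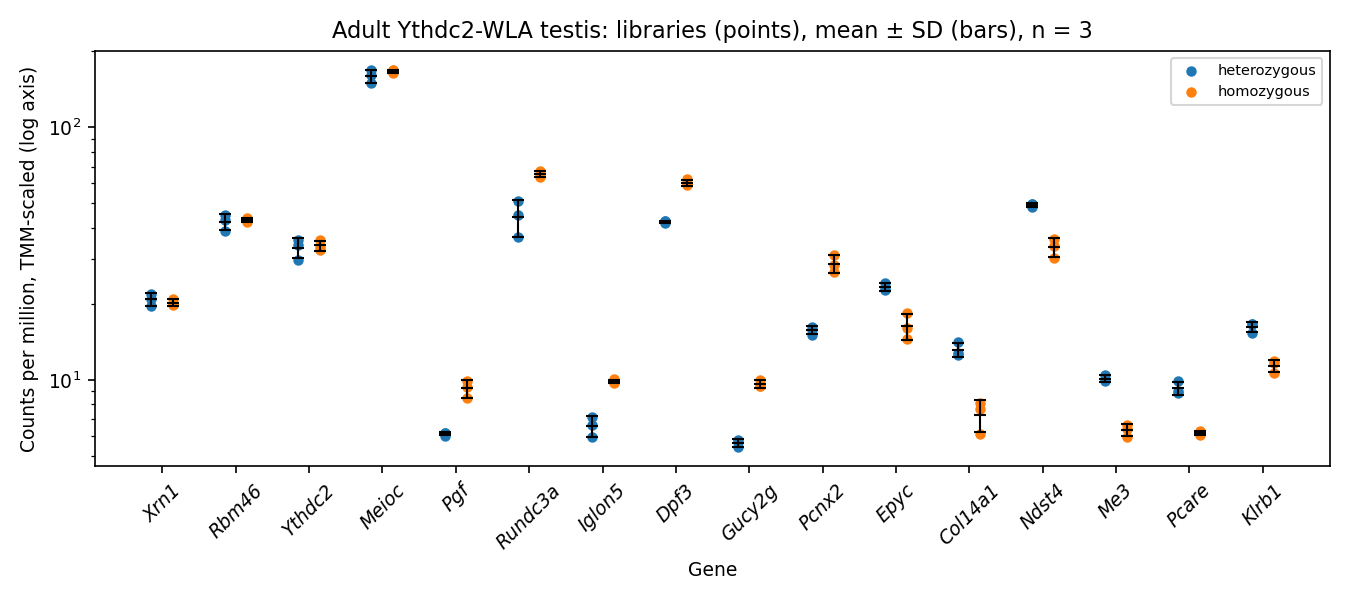
CPM scaled by TMM (y axis, log scale) of the 4 genes fixed in advance and the 12 named changed genes in adult WLA testis; points are libraries, bars the mean ± SD of 3 libraries. Ythdc2 has means of 33.3 and 34.1, and Pcnx2 of 15.7 and 28.9.

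Sertoli and Leydig cell markers lay higher in homozygous adult testis when genes were ranked, without a single member past 0.05, over all genes or adjusted over the list alone. Sertoli cell markers had a median log2 fold change of 0.12 with 21 of 22 above 0 (cameraPR, adjusted p 0.000356; adjusted p 0.96 with an estimated correlation). Leydig cell markers had one of 0.15 with 13 of 15 above 0 (adjusted p 0.0391), mitochondrially encoded genes one of 0.10 with 13 of 13 above 0 (adjusted p 0.0338) and round spermatid genes one of -0.05 with 17 of 25 below 0 (adjusted p 0.0354), with 1 round spermatid gene past 0.05 adjusted over the list alone. With an estimated correlation these calls were lost as well, each with an adjusted p of 0.96. Other somatic lists did not pass cameraPR, among them peritubular myoid markers (median 0.13, 8 of 10 above 0, adjusted p 0.0707), macrophage markers (median -0.10, 11 of 15 below 0, adjusted p 0.685) and endothelial markers (median 0.02, 7 of 12 above 0, adjusted p 0.967). Higher values were not particular to somatic lists. Differentiating spermatogonia (median 0.07, 15 of 15 above 0, adjusted p 0.0639) and undifferentiated spermatogonia (median 0.15, 16 of 22 above 0, adjusted p 0.105) did not pass cameraPR. Nor did DNA replication genes (median 0.085, 21 of 27 above 0, adjusted p 0.0751). Pachytene (median -0.02, adjusted p 0.959) and elongating spermatid genes (median -0.04, adjusted p 0.329) lay lower without passing. The mean log2 level of the Sertoli list was 4.68 ± 0.09 in heterozygous and 4.80 ± 0.017 in homozygous libraries (SD, n = 3 each; exact permutation test, two-sided p 0.1, the smallest that 3 against 3 allows). That of the Leydig list was 5.02 ± 0.317 and 5.22 ± 0.125 with overlapping groups (SD, n = 3 each; exact permutation test, two-sided p 0.4). The groups also overlapped for mitochondrially encoded genes (exact p 0.4) and round spermatid genes (exact p 0.7). As for the Sertoli list, they did not overlap for differentiating spermatogonia and DNA replication genes (exact p 0.1 for each). Chance alone parts 3 against 3 libraries in 10% of cases. The closest Sertoli levels of the groups were 4.781 in a heterozygous and 4.786 in a homozygous library.

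The number of calls changed when any 1 library was left out. Such a refit has 3 animals against 2, so a lost call can come from lower power. Of the 12 named genes, Pcnx2 and Dpf3 passed without each of the 6 libraries in turn, and the other 10 lost the call in 3 to 5 of these 6 refits. None of the 12 changed direction. Without heterozygous replicate 1, which stood closer to the homozygous libraries than to its own group, 1917 features passed; without heterozygous replicate 2 or 3, 4 and 15 passed, and without homozygous replicate 1, 2 or 3, 3, 4 and 4 passed. A DESeq2 Wald test called 218 and the authors' deposited table (DESeq2) 195, which held all 53. Against the juvenile knockout, adult fold changes had a Spearman correlation across genes of -0.067 with day 8 and 0.034 with day 10 total RNA effects. Among genes measured in both, 13 adult and 3 day 8 calls at 0.05 were higher and 11 and 4 were lower, with 0 shared where independent lists would share 0.00287 and 0.00324 (one-sided Fisher's exact test, p 1 for each). With so few calls, that test could not show whether the 2 alleles share changes. Day 10 had 0 calls at 0.05. At 0.15, 1 higher gene was shared with adult (expected 0.745, p 0.528) and 0 lower genes (expected 0.49, p 1), and 1 gene was called in opposite directions.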

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

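The tests of position, of germ cell lists and of slopes below were chosen after the results were seen; the test of shared translation calls was written before its value was known. Knockout effects of both ages were compared by ranking the difference of each gene's effects (cameraPR), and 11 of 78 list differences passed an adjusted p of 0.05. In total RNA, the median change from day 8 to day 10 was -0.21 for early meiotic genes (adjusted p 5.05e-66), 0.14 for differentiating spermatogonia (6.94e-07), 0.14 for retinoic acid genes (2.1e-09), 0.32 for red blood cell genes (1e-16), 0.10 for endothelial markers (5e-04), 0.049 for nuclear oxidative phosphorylation genes (0.000176) and 0.043 for ribosomal protein genes (0.00313). In footprints it was -0.22 for early meiotic genes (4.99e-38), 0.11 for differentiating spermatogonia (0.019), 0.34 for red blood cell genes (0.000306) and 0.19 for replication-dependent histones (7.09e-13). These p-values rank genes against each other and hold no spread between animals, and those of the red blood cell list rest on 5 genes. They therefore cannot show that the knockout effect differs with age. Age and animals differ together in this design, and controls were wild type at day 8 and mostly heterozygous at day 10.

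Of the 100 genes with the largest total RNA effects at day 8, 27 lie on chromosome 18, which holds 2.63% of genes (one-sided Fisher's exact test across genes, p 3.13e-20), and 25 lie within 20 Mb of Ythdc2, 16 of them higher. Reads shared within the protocadherin cluster do not account for it, since without Pcdh genes the region still stood at percentile 100 of windows elsewhere. At day 10, in other animals, the region was again at percentile 100, and among the 100 largest day 8 effects of genes measured at both ages, 25 of 26 region genes kept their sign, against 50 of 72 genes from other chromosomes. A segment of chromosome linked to the knockout allele may be the source, although no genotype along the chromosome was examined and whether any animal carries such a segment is unknown; a response of these genes to loss of YTHDC2 predicts the same 25 and cannot be told apart from it, because both would go with the knockout genotype. In adult WLA testis the region stood at percentile 72.9.

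Early meiotic genes were lower at day 10 (median -0.30). A loss of germ cells of every stage would lower other germ cell lists too, but the undifferentiated, differentiating and piRNA lists together had a median of 0.011 (60 genes, quartiles -0.03 and 0.06), which argues against it. Footprints lower than the RNA change gives stayed open, with a median difference of -0.074 (quartiles -0.15 and -0.02) on effects whose scale may differ between the assays. Fewer cells in meiotic prophase, or prophase cells with less of these mRNAs, cannot be told apart here, because pachytene genes, which are used later, had a median of -0.027 at this age. A small difference in developmental age between litters was not tested.

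Translation calls at day 8 may come from regression slopes fitted on few residual degrees of freedom: over the 196 calls measured at both ages, slopes of day 8 and of the other animals of day 10 had a Spearman correlation across genes of 0.006 (0.018 over all genes), though slopes that truly differ between the ages would give the same. The slope lay outside -1 to 2 for 100% of the 202 calls and 96% of the authors' class at day 8, and for 98.5% and 83% at day 10, but it is worked back from the translation effect, so these shares restate the size of that effect and decide nothing. In the day 10 animals 41.8% of the 196 day 8 calls had such a slope, against 48.8% of all genes. The squared within-group correlation implied by the table had a median over all genes of 0.479 at day 8, where unrelated values give 0.5 with 2 residual degrees of freedom and 0.163 with 4; a batch term in the authors' model would leave 2, which could not be checked, and with 4 the values would be more related than chance gives. A change in translation shared by both ages was neither shown nor excluded, with 4 genes called in the same direction at 0.05 where independent lists would share 1.34 higher and 1.3 lower (p 0.742 and 0.142), and 11 higher and 14 lower at 0.15 where they would share 6.69 and 7.2 (p 0.0732 and 0.0136).

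For the 53 features past the threshold in adult WLA testis, 1 of 10 splits of the 6 libraries, the real one, gave as many, and the highest other split gave 0; 10 splits are too few for a share under 0.05.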

How the results depend on the processing

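The numbers 1 to 3 in the adult column names are not tied to animals, so same-numbered columns were not taken as pairs. Same-numbered columns had correlations of their deviations from the group means of 0.177, -0.004 and 0.117. Columns with unlike numbers had between -0.15 and 0.061, so these values do not exclude pairs. With the number as a replicate block, chosen after seeing the data, 355 features passed in place of 53. The juvenile tables hold no values per animal, so the animal as a block, leave-one-out fits, heterozygous-only controls, other scalings, a level filter and a second p adjustment were not run on them, and age was not run as an adult covariate. Adult edgeR calls (53) became 5, 159 and 342 at adjusted p of 0.01, 0.1 and 0.15, 7 with an absolute log2 fold change of at least 1, 595 with no filter, 218 with DESeq2 and 195 in the authors' deposited table, an alternative chosen after seeing the data. Leaving out 1 library gave between 3 and 1917 calls; the cause was not tested. The 12 named adult genes lost the call in 45 of 72 refits without 1 library and in 0 of 60 others, and 0 changed direction.

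Day 8 total RNA calls in the authors' deposited table (8) became 5, 18 and 20 at 0.01, 0.1 and 0.15 and 0 with the minimum fold change. Day 10 total RNA calls (0) became 24 at 0.1 and 198 at 0.15, and day 10 footprint calls (0) became 4 at 0.15. Translation calls of day 8 (202) became 72, 334 and 464 at these thresholds, 85 with the minimum fold change, and 128 with the sign of footprint minus total RNA; those of day 10 (398) became 147, 669, 910, 144 and 252. The authors' class, which changes both the adjusted p limit (up to 0.099) and the effect limit, held 25 and 53, of which 10 and 23 were among these calls. Centring on the median changed no count. Shared calls of both ages went from 0, with no day 10 call to share, to 6 in total RNA at 0.15, or 2 without genes within 20 Mb of Ythdc2, an alternative chosen after seeing the data. In translation they went from 4 to 25, and those of adult and day 10, with no day 10 call at 0.05, from 0 to 1.

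Of 25 list calls, 18 were kept with a preset correlation of 0.05, 21 in the rank version and 25 with members in no other list, and none changed direction in these. Among adult genes at or above the median level 2 lists passed in place of 4. With footprint minus total RNA, 4 translation lists passed in place of 1, and the meiotic list of day 8 did not (adjusted p 0.9). The meiotic list in day 8 footprints was lost with the score of the adjusted p (0.105), and the adult Sertoli list with fold changes as the ranking (0.107) or an estimated correlation (0.96). The meiotic list passed in total RNA at both ages under each list alternative run.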

Other observations

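Several genes of fat cells were higher in total RNA of knockout testis at day 8. Fabp4 (0.57, adjusted p 0.0218) and Car3 (0.65, adjusted p 0.00105) passed 0.05 in the authors' deposited table, and Adipoq (0.41, adjusted p 0.08) did not. A list of fat cell markers was written after these were seen, so the genes already looked at were left out of its tests. The other 15 markers had a median of 0.04 in day 8 total RNA with 12 above 0 (cameraPR, p 0.00375), and at day 10 14 of them had one of 0.04 with 10 above 0 (p 0.0939). In footprints their median was 0.06 at day 8 with 13 above 0 (cameraPR, p 0.000146) and -0.049 at day 10 with 6 above 0 (p 0.761). Their translation effects had medians of 0.081 at day 8 (p 0.862) and -0.115 at day 10, where 3 of 14 lay above 0 (p 0.0469).

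Clec2d had total RNA effects of 0.69 at day 8 and 0.55 at day 10 in the authors' deposited table, with footprint effects of 0.05 and -0.03. Marchf3, on chromosome 18, had total RNA effects of 0.64 and 0.45 in the authors' deposited table, with footprint effects of -0.71 and -0.75.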
